A study of Mus musculus with 26 samples.

How the data were processed

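RNA sequencing of mouse white adipose tissue was analysed in 26 libraries from C57BL/6 mice. The labels give 3 groups, Ctrl, ABX and SZ-ABX, in each of 2 tissues. Subcutaneous white adipose tissue (scWAT) had 6 Ctrl, 5 ABX and 6 SZ-ABX libraries. Visceral white adipose tissue (pgVAT, read here as perigonadal) had 3 libraries in each group. ABX is read as the antibiotic-treated group from the series text, and the labels do not say what SZ stands for. According to the series text, mice were housed at 23 °C and antibiotics started at 8 to 9 weeks of age for 3 to 4 weeks. The labels describe total RNA from RNeasy kits, libraries from a NEBNext Ultra kit named there as a DNA kit, and 150 bp paired-end reads from an Illumina HiSeq X instrument.

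The deposited tables hold raw counts of reads per Ensembl gene, one column per library, and no normalization by the authors was found in them. The values were checked to be whole numbers with column totals that differ between libraries. The submitters' processing notes name STAR, HTSeq, DESeq2 and the mm10 genome build without versions, roles or order. The annotation release and the strand setting of the counting are not stated there. Each table holds 53801 genes, and 53620 identifiers were matched to a symbol. No pair of libraries was identical (0 pairs). Library totals ranged from 9720644 to 15722905 counts, and 21938 to 24256 genes had counts in a library. Gene positions are those of GENCODE release M21 on GRCm38, the assembly of mm10.

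Each tissue was fitted alone, with the 3 groups in one model so that they share one estimate of the spread. Counts were normalised by TMM, genes with low counts were removed by filterByExpr, and the groups were compared by the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. This left 16625 genes in scWAT and 16196 in pgVAT. Differences of an effect between the tissues, and of Ctrl scWAT from Ctrl pgVAT, were tested in one fit of all 26 libraries with 17909 genes. That fit takes the libraries as independent, and the labels do not state whether equal numbers in the tissues mark the same mouse. The tissues stand in separate tables, so that tissue cannot be told apart from any batch shared by a table. Levels are CPM, counts scaled to the TMM-adjusted library total, given as mean ± SD, and fold changes are on the log2 scale with their standard error (SE). The p-values measure the spread between the samples as the labels give them, and nothing in the labels states that the libraries come from separate animals.

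Gene lists were fixed before the data were examined, as were the tests, the rule for named genes and the settings listed as fixed beforehand. The 33 lists cover thermogenic, mitochondrial, lipid, immune and matrix programmes and markers of cell types and of neighbouring tissues. Each was tested with camera of limma 3.58.1 on voom log2 CPM with a preset correlation of 0.01, adjusted over the lists of a comparison. The test was repeated with an estimated correlation and with fry. For each list the number of genes called over all genes tested is given beside the number adjusted over the list alone. After the data had been seen, the mean log2 CPM of each list was taken as a score per library and compared by a two-sided exact permutation test. With 3 libraries against 3, this test cannot go below an exact p of 0.10.

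The named genes of a comparison are 10 fixed genes of thermogenesis and adipocytes, the 8 called genes with the largest increase and the 8 with the largest decrease, and up to 4 members of each called list. Genes with a mean log2 CPM under 1 and predicted genes, pseudogenes and receptor segments were left out of the largest changes. For the tissue tests they are the identity lists and the 5 genes each way with the smallest adjusted p.

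The fits were first tested on simulated counts of the same size. In scWAT, 50.7% of genes changed by 1.5 fold, 76.1% of those changed by 2 fold and 98.5% of those changed by 4 fold were called between ABX and Ctrl. In pgVAT the shares were 22.4%, 61.2% and 87.9%, and 0 genes were called between the unchanged simulated groups. Changes were placed only in genes with a mean log2 CPM over 1, and each gene was drawn independently. Differences in tissue content shared by many genes of a library were therefore not simulated, and the shares do not cover them.

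Settings fixed beforehand were size factors of the RLE kind, no filter on low counts, DESeq2 1.42.0, voom with quality weights, a fold threshold, a fit of the 2 groups alone, the replicate number as a block, the B cell score as a covariate, and each library left out in turn. Removal of a trend on exon length and GC content, the muscle score as a covariate, the omission of the libraries high in muscle transcripts and the permutation of list scores were chosen after the data had been seen. ABX and SZ-ABX share their controls, so 20 simulations of unchanged groups and 20 divisions of the 6 scWAT controls into sets of 3 were run beside their comparison. Results were also set against other splits of the same libraries, with 100 splits drawn where more existed. Scores, intervals and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Intervals of single-library shares are 95% Wilson intervals and cover counting error only.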

Results

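The series concerns the loss of the gut microbiota under antibiotics and the thermogenic capacity of beige fat, the heat-producing adipocytes that appear within white fat. Bulk RNA-seq counts were compared between control (Ctrl), antibiotic-treated (ABX) and SZ-ABX libraries in subcutaneous (scWAT) and visceral (pgVAT) white fat. Libraries held 9720644 to 15722905 counts.

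In scWAT, transcripts of fatty acid oxidation were higher in ABX (n = 5) than in Ctrl (n = 6), and the call for these genes was the strongest among the metabolic lists. Acadm and Acadl, which encode acyl-CoA dehydrogenases of mitochondrial fatty acid oxidation, rose by log2 fold changes of 0.55 (SE 0.10, adjusted p = 0.0324) and 0.57 (SE 0.12, adjusted p = 0.0478). Etfa and Etfdh, which pass electrons from these enzymes to the respiratory chain, rose by 0.51 and 0.56. Of 25 genes on the list, 7 rose over all genes tested and 0 fell, while 18 rose and 1 fell when adjusted over the list alone. Acadm, Acadl, Etfa and Etfdh each lost their call without 8 to 13 of the 17 libraries, left out in turn (log2 fold changes 0.46 to 0.61, adjusted p up to 0.0973). Without ABX 2 or ABX 3 edgeR called 0 genes over all genes tested. Nor were these 4 genes called with the B cell score as a covariate (0.44 to 0.57, adjusted p up to 0.093). The list rose as a group (median 0.44, camera adjusted p = 2.92e-15), with an adjusted p = 0.506 with an estimated correlation and of 0.0291 by fry. Its score was 7.95 ± 0.13 in ABX and 7.54 ± 0.11 in Ctrl (mean log2 CPM ± SD), a difference of 0.42 (SE 0.074) with no overlap between the groups. The exact permutation p of this score was 0.00217, the smallest that 462 splits can give with n = 5 and n = 6 (adjusted p = 0.0179).

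Genes of lipolysis and markers of mature adipocytes were also higher in ABX scWAT than in Ctrl. Hcar2, a receptor that restrains lipolysis, rose from 47.8 ± 5.53 CPM in Ctrl to 76.7 ± 11.9 CPM in ABX (log2 fold change 0.68, SE 0.10, adjusted p = 0.0186). Its gene, ENSMUSG00000045502, lies on chromosome 5 from 123863570 to 123865499. On the lipolysis list 2 of 17 genes rose, namely Pnpla2, the adipose triglyceride lipase (0.42, SE 0.10), and the carboxylesterase gene Ces1f (0.59, SE 0.13), and 7 rose when adjusted over the list alone. On the adipocyte list Pparg, the master regulator of adipocyte differentiation, rose (0.39, SE 0.086), and 12 of 20 genes rose when adjusted over the list alone. Hcar2 lost its call without Ctrl 2, ABX 2 or ABX 3 (adjusted p up to 0.0623). Pnpla2, Ces1f and Pparg lost theirs without 12 or 13 of the 17 libraries (adjusted p up to 0.108), at log2 fold changes of 0.40 to 0.45, 0.48 to 0.64 and 0.35 to 0.44. They lost it with the B cell score too, at 0.36, 0.45 and 0.33 (adjusted p up to 0.106). Lipolysis rose as a list (median 0.35, camera adjusted p = 4.91e-06), as did adipocyte markers (median 0.35, camera adjusted p = 1.38e-08), each with an adjusted p = 0.506 with an estimated correlation. The lipolysis score did not overlap between the groups, at 8.46 ± 0.076 in ABX and 8.17 ± 0.12 in Ctrl (exact permutation p = 0.00217, adjusted p = 0.0179). The adipocyte score was higher by 0.28 (SE 0.10, exact permutation adjusted p = 0.107), and both lists hold Plin1, Lipe and Aqp7. Whether a higher adipocyte share carried the rise of fatty acid oxidation and lipolysis genes was not tested. The nuclear-encoded respiratory chain rose as a list (median 0.34, camera adjusted p = 1.72e-12), with an adjusted p = 0.61 with an estimated correlation. Of its 33 genes 32 were higher and 0 were called, and 3 rose when adjusted over the list alone.

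The thermogenic list, the group the series is about, was higher in ABX than in Ctrl scWAT at the median (0.33), with 19 of 24 genes higher. It rose by camera (adjusted p = 0.00914), with an adjusted p = 0.62 with an estimated correlation and of 0.349 by fry. None of its members was called (0 genes by edgeR), and 1 rose when adjusted over the list alone. Ucp1, the uncoupling protein of brown and beige mitochondria (ENSMUSG00000031710, chromosome 8, 83290352 to 83298452), had 330 ± 193 CPM in ABX and 186 ± 181 CPM in Ctrl, a log2 fold change of 0.82 (SE 0.68, adjusted p = 0.519). Ppargc1a, a coactivator of mitochondrial genes, had 16.6 ± 2.73 CPM in ABX and 11 ± 3.57 CPM in Ctrl (0.60, SE 0.30, adjusted p = 0.282). Cidea (0.27), Dio2 (0.27), Cox8b (0.59), Cox7a1 (0.47), Elovl3 (0.20) and Prdm16 (−0.08) were not called either, nor were the adipokine genes Adipoq (0.25) and Lep (−0.84). Dio2 was low in ABX 2 (3.12 CPM) and stood at 0.54 without it, at 0.63 without Ctrl 4, at 0.077 without Ctrl 6 and at 0.69 with the B cell score, each time uncalled. Ppargc1a stood at 0.70 without ABX 2. The difference of the thermogenic score was 0.26 (SE 0.29, exact permutation p = 0.379), so that it lay within the spread between libraries. The call was lost without Ctrl 6 (median 0.25, adjusted p = 0.118) or ABX 1 (median 0.22, adjusted p = 0.0827). The median was 0.49 without ABX 2 (adjusted p = 2.95e-06), a library with a low thermogenic score, and 0.49 with the B cell score (adjusted p = 0.000103).

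**Figure D1:**
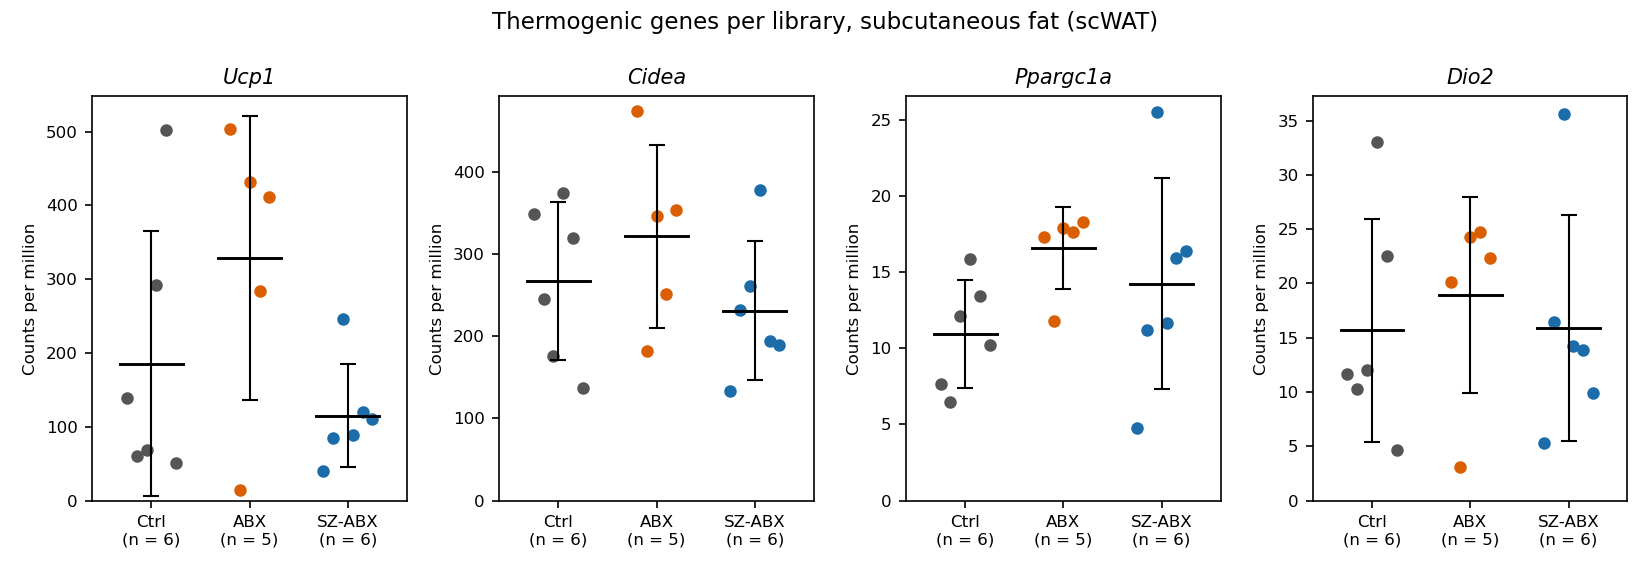
CPM of 4 thermogenic genes in scWAT, 1 point per library, with the mean and SD of each group. Ucp1 averaged 186 CPM in Ctrl, 330 CPM in ABX and 115 CPM in SZ-ABX, and the groups overlap in each of the 4 genes.

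Immune genes were lower in ABX than in Ctrl scWAT. Interferon-stimulated genes fell as a list (median −0.46, camera adjusted p = 1.42e-09), with an adjusted p = 0.506 with an estimated correlation. Of 25 genes 24 were lower, 0 were called by edgeR over all genes tested, and 17 fell when adjusted over the list alone. Examples are the antiviral GTPase Mx1 (−1.05, SE 0.30, adjusted p = 0.0849) and the nucleic acid sensor Zbp1 (−0.89, SE 0.25, adjusted p = 0.0859). The interferon score was 4.29 ± 0.085 in ABX and 4.74 ± 0.15 in Ctrl, without overlap (exact permutation p = 0.00217, adjusted p = 0.0179). The inflammatory list, with Tnf at −0.55 and Lbp at −0.68, fell at a median of −0.48 (camera adjusted p = 0.00823), with an adjusted p = 0.509 with an estimated correlation. The type 2 immunity list fell at a median of −0.40 (camera adjusted p = 0.0233), with an adjusted p = 0.599 with an estimated correlation. Neither list had a called gene (0 genes by edgeR), and 4 inflammatory and 0 type 2 genes fell when adjusted over the list alone. Their scores did not overlap between the groups either, with differences of −0.40 (exact permutation p = 0.00433, adjusted p = 0.0286) and −0.38 (exact permutation p = 0.00217, adjusted p = 0.0179). These 5 lists were the only ones of the 33 called by the permutation of scores in ABX against Ctrl scWAT, a test chosen after the data had been seen, and 11 had an unadjusted p under 0.05. The type 2 call by camera was lost without Ctrl 6 or ABX 3 (adjusted p up to 0.0825).

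Markers of immune cells fell as lists in ABX scWAT, at medians of −0.53 for macrophages (19 genes), −0.68 for T and NK cells (19 genes), −0.43 for B cells (18 genes) and −0.47 for MHC class II (11 genes). Camera gave adjusted p = 9.70e-05, 1.20e-06, 0.000154 and 5.72e-05, and with an estimated correlation the adjusted p = 0.62, 0.618, 0.62 and 0.62. In each of these lists 0 genes were called by edgeR, and adjusted over the list alone 1 T and NK gene fell and 0 in the others. Examples are the scavenger receptor Cd163 of macrophages (−0.71, SE 0.22) and the NK receptor subunit Klrd1 (−1.07, SE 0.26, adjusted p = 0.0624). Extracellular matrix genes fell at a median of −0.37 (camera adjusted p = 0.000839), with an adjusted p = 0.62 with an estimated correlation. Fibronectin, Fn1, had 298 ± 56.6 CPM in ABX and 547 ± 153 CPM in Ctrl (−0.88, SE 0.28, adjusted p = 0.11), and 0 of 24 matrix genes were called by edgeR or fell when adjusted over the list alone. Cell cycle genes fell at a median of −0.23 (camera adjusted p = 0.0195), with an adjusted p = 0.684 with an estimated correlation, 0 called genes and 0 when adjusted over the list alone. That call was lost without Ctrl 5, ABX 1 or ABX 4 (adjusted p up to 0.102). Subcutaneous fat pads can hold a lymph node, and with the B cell score as a covariate the calls of the cell cycle (median 0.026) and macrophage (median −0.33) lists were lost. The B cell score was itself lower in ABX by 0.47 (SE 0.29, exact permutation p = 0.117), so that this covariate may also remove a part of a group effect.

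In all, 122 of 16625 genes differed between ABX and Ctrl in scWAT by edgeR, 69 higher and 53 lower, with a median absolute log2 fold change of 0.54 and a largest of 1.32. Among the largest decreases were Sidt1 (−1.12, SE 0.22, adjusted p = 0.0327) and Phf24 (−1.05, SE 0.20), followed by the adaptor gene Gab3 (−0.99), the phospholipid flippase gene Atp8b4 (−0.97) and the vesicular nucleotide transporter Slc17a9 (−0.90). Ikbke, a kinase of innate immune signalling, fell by 0.80 on the log2 scale, and Naip5, a sensor of bacterial flagellin with close paralogs, fell by 0.78. Among the largest increases were Osbp2 (0.90), which encodes an oxysterol-binding protein, Rbp7 (0.71), which encodes a retinol-binding protein, and the soluble epoxide hydrolase gene Ephx2 (0.69, from 438 ± 82.5 to 708 ± 121 CPM). Bbof1 (0.65), the tubulin-associated Tppp (0.63) and the selenophosphate synthetase gene Sephs2 (0.62) completed the named increases. Mccc1os (0.90) and Arhgap27os3 (−0.97) lie on the strand opposite another gene, and the strand of counting is not stated. DESeq2 called 831 genes, 121 of them shared, voom with quality weights 653, and a fit of ABX and Ctrl alone 447, 142 were called with RLE size factors and 126 with a trend on length and GC content removed. The count was 38 without a filter on low counts, 7 with at least a 2 fold change, 63 with the muscle score and 5 with the B cell score as a covariate. Muscle transcripts were high in Ctrl 3 (score 9.00), SZ-ABX 3 (7.68) and SZ-ABX 6 (7.43), and 46 genes were called without these libraries. Left out in turn, 14 of the 17 libraries moved the count by over 1.5 times. It was 14, 2, 34, 5 and 60 genes without Ctrl 1, 2, 3, 4 and 5. It was 56, 0, 0, 9 and 8 without ABX 1, 2, 3, 4 and 5, and 30, 292, 55 and 253 without SZ-ABX 3, 4, 5 and 6.

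**Figure D2:**
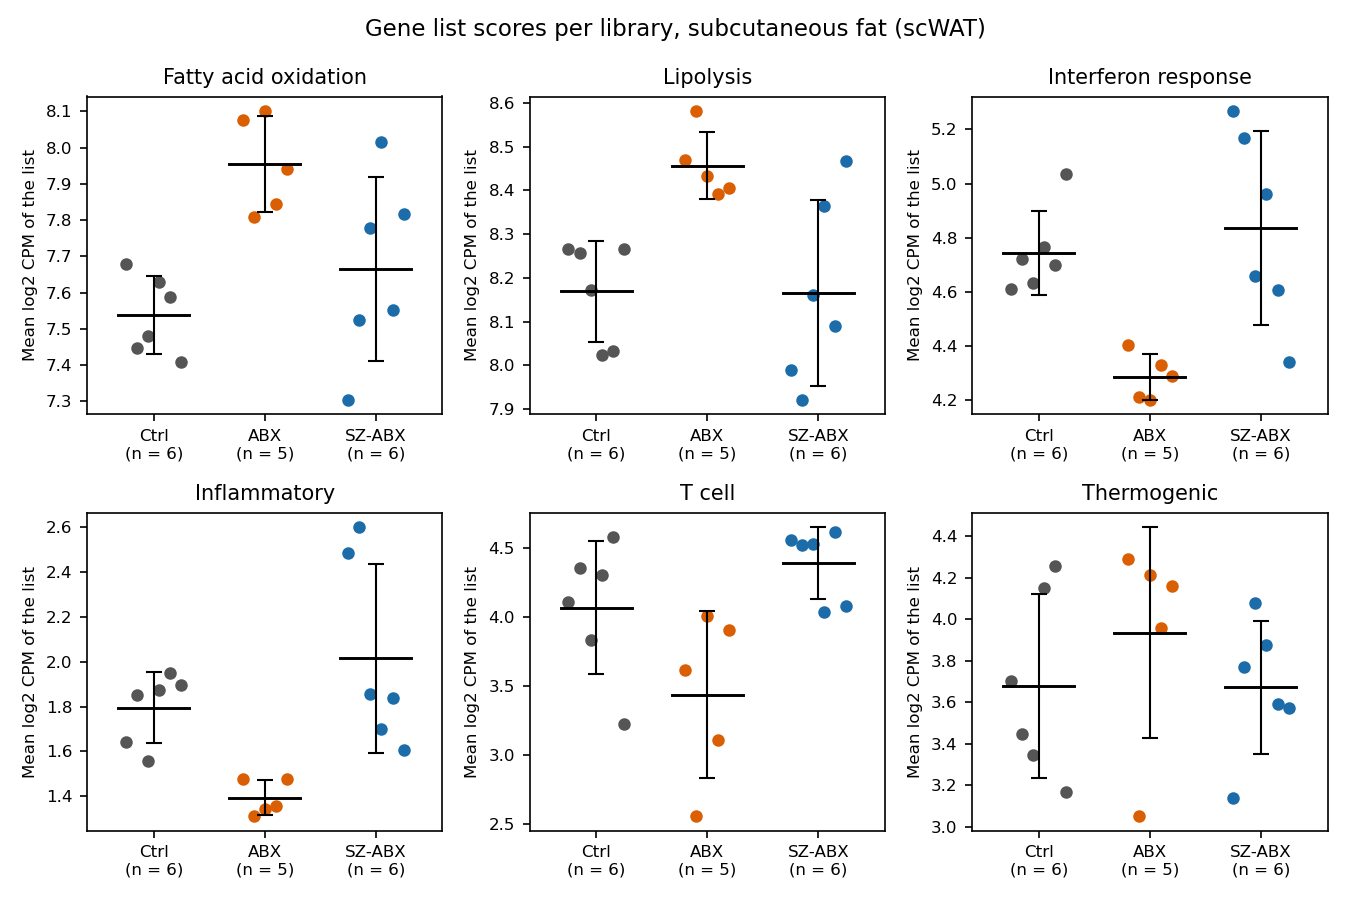
Scores (mean log2 CPM of the list members) of 6 gene lists in scWAT, 1 point per library, with the mean and SD of each group. ABX and Ctrl do not overlap in fatty acid oxidation (7.95 against 7.54), lipolysis, interferon response (4.29 against 4.74) and inflammatory genes, and they overlap in T cell and thermogenic genes.

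SZ-ABX scWAT (n = 6) showed no gene past the threshold against Ctrl (n = 6) by edgeR. By edgeR 0 of 16625 genes were called, with 1519 at an unadjusted p under 0.05 and a smallest adjusted p of 0.141. DESeq2 called 28 genes, 6 higher and 22 lower, and voom with quality weights 0. Leaving out Ctrl 5 gave 13 called genes, and leaving out ABX 4, SZ-ABX 3 or SZ-ABX 5 gave 1 each. Ucp1 had 115 ± 69.3 CPM in SZ-ABX and 186 ± 181 CPM in Ctrl (−0.69, SE 0.66, adjusted p = 0.765), Prdm16 12.3 ± 3.64 and 16.9 ± 4.35 CPM (−0.46, SE 0.21), and Lep 95.5 ± 82.2 and 230 ± 101 CPM (−1.27, SE 0.44, adjusted p = 0.45). SZ-ABX 6 was high in Lep (256 CPM), and without it the log2 fold change was −1.86 (adjusted p = 0.267). The thermogenic list had a median of −0.05 and a mean of 0.037 (camera adjusted p = 0.965), with 11 genes higher and 13 lower. The median was −0.30 without the libraries high in muscle transcripts (adjusted p = 0.31), −0.15 without Ctrl 6, 0.0045 without Ctrl 5 and 0.050 without SZ-ABX 1.

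Some lists still moved in SZ-ABX against Ctrl scWAT by camera, with small medians. Endothelial markers fell (median −0.23, camera adjusted p = 2.02e-06), with an adjusted p = 0.598 with an estimated correlation. Of 14 genes 0 were called by edgeR, and adjusted over the list alone 7 fell and 1 rose, with the angiopoietin receptor Tek at −0.47 (SE 0.12) and Tie1 at −0.42 (SE 0.12). Sterol synthesis genes fell (median −0.21, camera adjusted p = 1.05e-05), as did lipogenic genes (median −0.16, camera adjusted p = 0.0185), each with an adjusted p = 0.953 with an estimated correlation. Hsd17b7 (−0.65) is an example of the first list, in which 2 genes fell when adjusted over the list alone, and Scd2, a fatty acid desaturase (−0.90), of the second, in which 0 did. Fatty acid oxidation rose (median 0.15, camera adjusted p = 0.00508), and so did cell cycle genes (median 0.35, camera adjusted p = 0.000203), B cell markers (median 0.39, camera adjusted p = 0.00565) and T and NK cell markers (median 0.28, camera adjusted p = 0.000613), each with an adjusted p = 0.953 with an estimated correlation and 0 genes called or past the list-alone threshold. Progenitor (median −0.13), nerve (median −0.17) and subcutaneous identity genes (median −0.27) fell, with camera adjusted p = 0.0295, 0.0206 and 0.0445 and adjusted p = 0.953, 0.953 and 0.598 with an estimated correlation, and 1 subcutaneous identity gene fell when adjusted over the list alone. The muscle list was called "Up" by camera (adjusted p = 0.0445, and adjusted p = 0.953 with an estimated correlation) although its median was −0.15 and its mean −0.24. Its score was 5.44 in SZ-ABX and 4.37 in Ctrl, a difference of 1.06 (SE 1.46, exact permutation p = 0.481).

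Calls of SZ-ABX against Ctrl in scWAT were lost for most of these lists when 1 library was left out. Fatty acid oxidation was lost without SZ-ABX 4 or 6 (adjusted p up to 0.301), T and NK cells without Ctrl 6 (0.123), and B cells without Ctrl 6, SZ-ABX 1 or SZ-ABX 2 (up to 0.123). Lipogenesis was lost without Ctrl 1, Ctrl 4, SZ-ABX 1, SZ-ABX 5 or SZ-ABX 6 (adjusted p up to 0.167), progenitors without Ctrl 5, Ctrl 6, SZ-ABX 4 or SZ-ABX 6 (up to 0.418), and nerve without Ctrl 6, SZ-ABX 2 or SZ-ABX 4 (up to 0.123). The muscle call was lost without Ctrl 1, 2, 5 or 6, ABX 2, or SZ-ABX 1, 3 or 6 (adjusted p up to 0.708), and subcutaneous identity without Ctrl 2, 3, 4, 5 or 6, ABX 2, or SZ-ABX 1, 2, 4 or 6 (up to 0.123). The endothelial, sterol synthesis and cell cycle calls were kept in 17 of 17 such fits. Their scores were not called by the exact permutation test (adjusted p = 0.607, 0.672 and 0.672). Other splits of these libraries gave a median of 11 called lists, as many as the real one. The T and NK cell (median 0.099), nerve (median −0.12) and subcutaneous identity (median −0.23) calls were lost with the B cell score as a covariate.

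Interferon and lymphocyte genes were higher in SZ-ABX (n = 6) than in ABX (n = 5) scWAT. Of 220 called genes 192 were higher and 28 lower, with a median absolute log2 fold change of 0.84 and a largest of 2.40. Among the named genes that were called, the chemokine gene Ccl7 rose most (2.26, SE 0.53, adjusted p = 0.0466; 5.60 ± 4.95 against 1.16 ± 0.665 CPM), followed by Oas3 (1.98). The lymphocyte signalling adaptor Sh2d1a (1.57), Samd3 (1.54), and the interferon-inducible Phf11a (1.56), Ifi206 (1.56) and Ifit1bl1 (1.54) rose as well, the last 3 and Oas3 being members of families with close paralogs. Of 25 interferon genes 4 rose, namely Mx1 (1.53, SE 0.30), Zbp1 (1.18), Oas2 (1.16) and Xaf1 (0.52), and 20 rose when adjusted over the list alone. The list rose (median 0.50, camera adjusted p = 3.78e-10), with an adjusted p = 0.454 with an estimated correlation. Among T and NK cell markers Klrd1 rose (1.39, SE 0.26, adjusted p = 0.0354), from 4.75 ± 0.928 CPM in ABX to 12.5 ± 2.58 CPM in SZ-ABX. Of these 19 genes 17 rose when adjusted over the list alone (median 0.92, camera adjusted p = 3.06e-11), with an adjusted p = 0.454 with an estimated correlation. Mx1, Zbp1, Oas2, Xaf1, Klrd1 and Ccl7 each lost their call without 7 to 13 of the 17 libraries (adjusted p up to 0.136). With the B cell score they stood at 0.89, 0.65, 0.92, 0.59, 0.99 and 1.12 in this order and were not called (adjusted p up to 0.622). Oas3, Sh2d1a, Samd3, Phf11a, Ifi206 and Ifit1bl1 lost their call without 7 to 12 of the 17 libraries. With the B cell score these stood at 1.08, 1.28, 1.04, 1.06, 0.80 and 0.99 in this order, and none was called.

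Further immune lists rose in SZ-ABX against ABX scWAT. The medians were 0.82 for B cells, 0.67 for macrophages, 0.62 for MHC class II, 0.65 for cell cycle genes and 0.49 for inflammatory genes, with camera adjusted p = 2.95e-08, 4.07e-06, 5.11e-07, 3.66e-07 and 0.0115. With an estimated correlation the adjusted p = 0.454 for each of these except macrophages, where it was 0.465. Adjusted over the list alone 16 of 18 B cell, 12 of 19 macrophage, 11 of 11 MHC class II, 12 of 20 cell cycle and 6 of 15 inflammatory genes rose and 1 inflammatory gene fell. Over all genes tested, 1 inflammatory gene rose, Ccl7, and 0 genes of the other 4 lists were called by edgeR. The interleukin 1 receptor antagonist gene Il1rn (2.02, SE 0.59, adjusted p = 0.0673) and the lymphoid homing receptor gene Ccr7 (1.24, SE 0.34, adjusted p = 0.0584) are examples. Scores of inflammatory and of T and NK cell genes did not overlap between the groups, with adjusted p = 0.0952 and 0.0714 in the exact permutation test, so that 0 of 33 lists were called by it and 11 had an unadjusted p under 0.05. With the B cell score as a covariate the MHC class II (median 0.045), cell cycle (median 0.12), inflammatory (median 0.40) and macrophage (median 0.29) calls were lost.

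Metabolic and thermogenic lists were lower in SZ-ABX than in ABX scWAT by camera, while the exact permutation of scores called none of them. Fatty acid oxidation fell (median −0.30, camera adjusted p = 2.95e-08), with an adjusted p = 0.454 with an estimated correlation. By edgeR 0 of its 25 genes were called, and adjusted over the list alone 14 fell and 1 rose. Acadm stood at −0.36 (SE 0.10, adjusted p = 0.0644). The fatty acid oxidation score differed by −0.29 (SE 0.12, exact permutation adjusted p = 0.149). The nuclear-encoded respiratory chain (median −0.26), mitochondrially encoded genes (median −0.24), lipolysis (median −0.30), adipocyte (median −0.28), endothelial (median −0.26) and lipogenic genes (median −0.25) fell as well, with camera adjusted p = 2.95e-08, 0.00262, 2.84e-05, 9.54e-07, 0.000822 and 0.0114. With an estimated correlation their adjusted p = 0.483, 0.483, 0.454, 0.454, 0.465 and 0.664. By edgeR 0 of these genes were called, and 3 lipolysis and 7 adipocyte genes fell when adjusted over the list alone. The thermogenic list fell (median −0.38, camera adjusted p = 0.0112), with an adjusted p = 0.487 with an estimated correlation and of 0.261 by fry. Of its 24 genes 21 were lower, 0 were called and 0 passed when adjusted over the list alone, with Ucp1 at −1.52 (SE 0.69, adjusted p = 0.2) and Otop1 at −0.61 (SE 0.22). The thermogenic score differed by −0.26 (SE 0.26, exact permutation p = 0.318), so that it lay within the spread between libraries. The thermogenic call was lost without ABX 1 (median −0.30, adjusted p = 0.0646) or SZ-ABX 1 (median −0.33, adjusted p = 0.0754). The median of the list was −0.58 without the libraries high in muscle transcripts (adjusted p = 0.00976), −0.53 with the B cell score and −0.52 without ABX 2. Lost as well was the lipogenic call without ABX 1, ABX 5, SZ-ABX 5 or SZ-ABX 6 (adjusted p up to 0.256). Lipolysis (median −0.10), adipocyte (median 0.0001) and endothelial (median −0.066) calls were lost with the B cell score as a covariate.

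Among the 28 genes that fell in SZ-ABX against ABX scWAT, the largest named decreases were Stac (−1.10, SE 0.21, adjusted p = 0.0354), the intermediate filament gene Nes (−0.86), the potassium channel gene Kcnk2 (−0.67), Filip1 (−0.66), Ppp1r3d (−0.65), Clic5 (−0.63), Ccdc85c (−0.58) and Slc9a3r2 (−0.53). DESeq2 called 1354 genes in this comparison, 218 of them shared, and voom with quality weights 1613, whereas a fit of the 2 groups alone called 12. The count was 200 with RLE size factors, 219 without a filter on low counts, 325 with a trend on length and GC content removed, 582 with the muscle score as a covariate and 73 with at least a 2 fold change. With the B cell score as a covariate 0 genes were called by edgeR, with 1308 at an unadjusted p under 0.05. The B cell score was itself higher in SZ-ABX (5.94) than in ABX (5.19, exact permutation p = 0.0628). As a covariate it may therefore remove a part of a group effect as well. Without the libraries high in muscle transcripts 781 were called. The count moved by over 1.5 times without 16 of the 17 libraries. It was 129, 114, 17, 585 and 501 genes without Ctrl 1, 2, 4, 5 and 6. It was 0, 0, 335, 0 and 135 without ABX 1, 2, 3, 4 and 5, and 0, 0, 0, 1770, 0 and 1444 without SZ-ABX 1, 2, 3, 4, 5 and 6.

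The effects of ABX and SZ-ABX in scWAT were set against each other across 16625 genes, which are not independent replicates. Their log2 fold changes against the shared controls correlated with a Pearson r of 0.219 and a covariance of 0.0188, and 0 genes were called in both. In the simulations all 3 groups, controls included, were drawn gene by gene around the mean of the controls. They gave a mean r of 0.483 and a covariance of 0.0281, above the observed values. Genes were drawn independently, so that structure shared by the genes of a real library is missing from this reference. With the controls divided so that each comparison had its own 3, the mean r over 20 divisions was −0.205 (SD 0.145) and the covariance −0.0311, so that the sign of the mean changed. Single divisions gave r from −0.453 to 0.104. The mean Spearman correlation was −0.047 (SD 0.13), and a mean of 49.9% of genes had the same sign, which shows little relation either way. In pgVAT r was 0.398 and the covariance 0.0519, against 0.501 and 0.0971 in the simulation, whereas the share of genes with the same sign was 70.7% against a simulated 66.8%. Its 3 controls were too few to divide, and part of the observed agreement may come from the shared controls.

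In pgVAT, respiratory chain genes were higher and matrix genes lower in ABX than in Ctrl (n = 3 each), as lists, while edgeR called 0 single genes (1326 at an unadjusted p under 0.05), DESeq2 46 and voom with quality weights 0. The 33 nuclear-encoded respiratory chain genes were each higher (median 0.32, camera adjusted p = 3.52e-22), with an adjusted p = 0.352 with an estimated correlation, and 20 rose when adjusted over the list alone. The first principal component of pgVAT held 53.1% of the variance and set Ctrl 3 (54.7), ABX 2 (37.8), SZ-ABX 1 (31.7) and SZ-ABX 3 (47.9) apart from the other libraries, all below 0. This division runs across the groups, its loadings had a Spearman correlation of 0.23 with GC content, and it was not used as a covariate. Ndufa4 stood at 0.50 (SE 0.12) and Cox7b at 0.49 (SE 0.13). Mitochondrially encoded genes rose (median 0.35, camera adjusted p = 5.41e-07), as did fatty acid oxidation (median 0.21, camera adjusted p = 8.71e-07), each with an adjusted p = 0.43 with an estimated correlation. There 1 mitochondrial gene rose and 1 oxidation gene fell when adjusted over the list alone. Extracellular matrix genes fell (median −0.52, camera adjusted p = 6.48e-19), with an adjusted p = 0.0749 with an estimated correlation and of 0.0336 by fry, and 17 of 24 fell when adjusted over the list alone. The collagen genes Col3a1 (−0.72, SE 0.14) and Col6a2 (−0.56, SE 0.10) are examples. Progenitor markers fell too (median −0.30, camera adjusted p = 0.000154), with an adjusted p = 0.0749 with an estimated correlation, 0.0336 by fry, and 2 of 14 genes down when adjusted over the list alone. Adipocyte markers rose (median 0.16, camera adjusted p = 0.000154), with an adjusted p = 0.352 with an estimated correlation, and 3 of 20 rose when adjusted over the list alone.

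Other lists were called by camera in ABX against Ctrl pgVAT as well, markers of neighbouring tissue among them. Mesothelial genes fell (median −0.88, camera adjusted p = 5.54e-05), as did visceral identity genes (median −0.73, camera adjusted p = 0.00408), each with an adjusted p = 0.464 with an estimated correlation, and both lists hold Wt1 (−0.48), Bnc1 (−0.93) and Lrrn4 (−1.01) among other shared genes. Muscle transcripts rose as a list (median 4.41, camera adjusted p = 0.0323), with an adjusted p = 0.626 with an estimated correlation. ABX 3 carried them (score 8.38), 7 of 8 rose when adjusted over the list alone, and without it the median was −0.29. The same library had the lowest mesothelial score of the ABX group (2.59, against 4.22 in ABX 1 and 4.68 in ABX 2). Its visceral identity score was the lowest as well (2.97, against 4.28 and 4.23). A large part of the fall of these 2 lists thus lay in ABX 3. Macrophage (median −0.20), MHC class II (median −0.22), type 2 immunity (median −0.35), interferon (median −0.25), B cell (median −0.40) and sterol synthesis genes (median −0.32) fell, and lipolysis (median 0.14) and erythroid genes (median 0.35) rose. Camera gave adjusted p = 4.88e-05, 0.000235, 0.00904, 0.0288, 0.0397, 0.0288, 0.0323 and 0.0491 in this order, and with an estimated correlation the adjusted p = 0.404, 0.402, 0.352, 0.672, 0.464, 0.672, 0.464 and 0.62. In these 8 lists 0 genes passed when adjusted over the list alone.

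By edgeR 0 of 16196 genes were called between ABX and Ctrl in pgVAT, with 1326 at an unadjusted p under 0.05 and a smallest adjusted p of 0.547. DESeq2 called 46 (25 higher, 21 lower) and voom with quality weights 0. The thermogenic list had a median of 0.079 (camera adjusted p = 0.373), and Cidea (0.06), Ppargc1a (0.092) and Cox8b (1.18, SE 0.40) were not called. The median was −0.036 with the muscle score, −0.037 without ABX 3 and −0.036 without Ctrl 3. It was 0.22 with the B cell score, where the list was called (adjusted p = 0.0113). The B cell score in pgVAT was low and did not overlap between ABX (0.57 to 0.79) and Ctrl (0.93 to 1.29). As a covariate it can hardly be told apart from the group there. Ucp1 had too few counts to be tested in pgVAT. Several calls of ABX against Ctrl pgVAT were lost when 1 library was left out. Sterol synthesis was lost without Ctrl 1 or ABX 1 (adjusted p up to 0.61), where the median reached 0.073, lipolysis without Ctrl 1, Ctrl 3, ABX 1 or ABX 3 (up to 0.312), interferon without Ctrl 1, Ctrl 2 or ABX 1 (up to 0.785). Also lost was type 2 immunity without Ctrl 2 (0.097). B cells were lost without Ctrl 1, Ctrl 3 or ABX 1 (adjusted p up to 0.202), erythroid genes without Ctrl 1, Ctrl 2, ABX 1, ABX 2 or SZ-ABX 1 (up to 0.319), muscle without Ctrl 1, 2 or 3 or ABX 3 (up to 0.791), mesothelial genes without Ctrl 3 (0.0668), and visceral identity without Ctrl 3 or ABX 3 (up to 0.227). With the B cell score as a covariate the lipolysis (median 0.062), interferon (median −0.11) and adipocyte (median 0.043) calls were lost, and sterol synthesis was called in the opposite direction (median 0.66).

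SZ-ABX pgVAT (n = 3) also had higher respiratory chain transcripts than Ctrl (n = 3). The 33 nuclear-encoded genes were each higher, and 31 rose when adjusted over the list alone (median 0.41, camera adjusted p = 5.46e-29), with an adjusted p = 0.55 with an estimated correlation. Cox7b had 86.8 ± 13.7 CPM in SZ-ABX and 50.6 ± 2.81 CPM in Ctrl (0.78, SE 0.13, adjusted p = 0.208), and Cox6a1 stood at 0.69 (SE 0.13). Mitochondrially encoded genes (median 0.36) and fatty acid oxidation (median 0.25) rose, with camera adjusted p = 4.07e-07 and 5.67e-08, an adjusted p = 0.55 with an estimated correlation for each, and 8 and 4 genes up and 0 and 1 down when adjusted over the list alone. Erythroid (median 0.71), glycolytic (median 0.27), lipogenic (median 0.29) and adipocyte genes (median 0.15) rose, and MHC class II (median −0.23), matrix (median −0.15) and endothelial genes (median −0.26) fell. Camera gave adjusted p = 0.00035, 0.00166, 0.00902, 0.0101, 0.00902, 0.0052 and 0.0439 in this order, and with an estimated correlation the adjusted p = 0.55, 0.593, 0.823, 0.55, 0.55, 0.55 and 0.55. Adjusted over the list alone 4 erythroid and 4 adipocyte genes rose and 4 endothelial genes fell, and 0 of the other 4 lists passed. The thermogenic list had a median of 0.24 (camera adjusted p = 0.18). It was 0.0061 without SZ-ABX 3, 0.081 without Ctrl 3, 0.11 without Ctrl 1 and 0.12 without a filter on low counts. It was 0.26 with the B cell score, where the list was called (adjusted p = 0.0436). Lep had 263 ± 77.9 CPM in SZ-ABX and 494 ± 264 CPM in Ctrl (−0.91, SE 0.38, adjusted p = 0.396).

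Over single genes, edgeR called 0 of 16196 between SZ-ABX and Ctrl in pgVAT, with 1905 at an unadjusted p under 0.05 and a smallest adjusted p of 0.208, whereas DESeq2 called 322 (269 higher, 53 lower) and voom with quality weights 0. In SZ-ABX against Ctrl pgVAT the lipogenic call was lost without Ctrl 3 or SZ-ABX 3 (adjusted p up to 0.671), glycolysis without SZ-ABX 3 (0.058), and adipocyte markers without Ctrl 3 or SZ-ABX 2 (up to 0.189). Lost as well were MHC class II without Ctrl 2, Ctrl 3 or SZ-ABX 2 (up to 0.18), matrix without Ctrl 2 or SZ-ABX 2 (up to 0.0984), and endothelial genes without Ctrl 2, ABX 1, ABX 2, ABX 3, SZ-ABX 2 or SZ-ABX 3 (up to 0.18). The adipocyte call was also lost with the B cell score as a covariate (median 0.12).

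Between SZ-ABX and ABX in pgVAT (n = 3 each), extracellular matrix genes were higher in SZ-ABX (median 0.26, camera adjusted p = 5.78e-10), with an adjusted p = 0.553 with an estimated correlation and 2 of 24 genes up when adjusted over the list alone. Col3a1 had 1195 ± 187 CPM in SZ-ABX and 765 ± 119 CPM in ABX (0.64, SE 0.14), and Col1a1 546 ± 172 and 282 ± 67.0 CPM (0.95, SE 0.31). Macrophage (median 0.24), lipogenic (median 0.31), mesothelial (median 0.75) and respiratory chain genes (median 0.11) rose, with camera adjusted p = 2.34e-05, 8.17e-05, 2.12e-05 and 2.34e-05 and adjusted p = 0.553, 0.593, 0.553 and 0.594 with an estimated correlation. Sterol synthesis (median 0.16), glycolysis (median 0.15), stress (median 0.19), erythroid (median 0.33), visceral identity (median 0.59) and epithelial genes (median 0.82) rose, and endothelial genes (median −0.13) and muscle transcripts (median −4.58) fell. Camera gave adjusted p = 0.00881, 0.0113, 0.00524, 0.0113, 0.00526, 0.0451, 0.00526 and 0.0113 in this order, and with an estimated correlation the adjusted p = 0.68, 0.594, 0.553, 0.593, 0.553, 0.553, 0.553 and 0.594. Of 8 muscle genes 7 fell when adjusted over the list alone, and the difference lay in ABX 3, without which the median was 0.08. The mesothelial score was also low in ABX 3 (2.59, against 4.22 in ABX 1 and 4.68 in ABX 2), and it was 4.8 to 4.9 in SZ-ABX. The thermogenic list had a median of 0.095 (camera adjusted p = 0.39), with Cidea at 0.66 (SE 0.58). Its median was −0.26 with the B cell score (adjusted p = 0.19) and 0.21 with the muscle score. It was 0.012 without ABX 1, 0.027 without SZ-ABX 3, 0.22 without SZ-ABX 2 and 0.24 without ABX 3.

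EdgeR called 0 of 16196 genes between SZ-ABX and ABX in pgVAT, with 859 at an unadjusted p under 0.05 and a smallest adjusted p of 0.922, DESeq2 called 1, and voom with quality weights 0. In this comparison the respiratory chain (adjusted p up to 0.508), lipogenic (0.14), sterol synthesis (0.359), glycolytic (0.489) and endothelial (0.064) calls were lost without ABX 1 or SZ-ABX 3, and stress genes without ABX 3 or SZ-ABX 1 (0.286). Further calls were lost for erythroid (0.279) and muscle genes (0.84) without ABX 3 or SZ-ABX 3, visceral identity without ABX 3 or SZ-ABX 2 (0.222), and epithelial genes without ABX 3, SZ-ABX 1, SZ-ABX 2 or SZ-ABX 3 (0.454). The epithelial call was also lost with RLE size factors and without a filter on low counts. With the B cell score as a covariate, sterol synthesis (median −0.30) and glycolysis (median −0.10) turned to the opposite direction with their calls, lipogenic genes had a median of −0.34 without a call, and the respiratory chain (median 0.004), erythroid (median 0.15), endothelial (median −0.023) and epithelial (median 1.08) calls were lost. The B cell score was at most 0.793 in ABX and at least 0.922 in SZ-ABX, so that this covariate can hardly be told apart from the group.

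**Figure D3:**
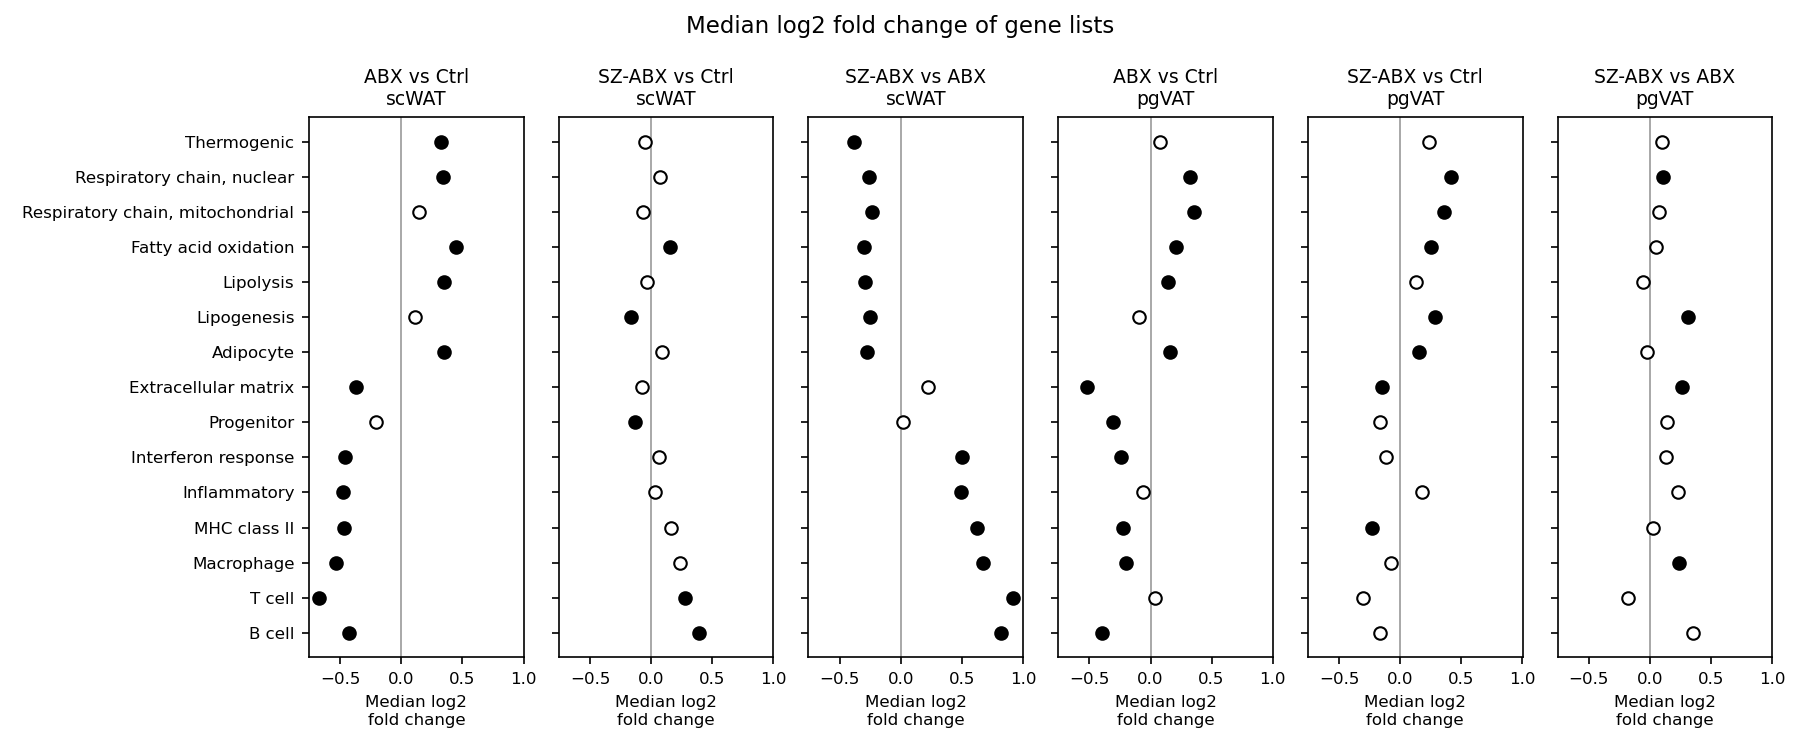
Median log2 fold change of 15 gene lists in the 6 comparisons, filled where the camera adjusted p with the preset correlation was under 0.05 and open where it was not. Fatty acid oxidation stood at 0.44 in ABX against Ctrl in scWAT and the nuclear-encoded respiratory chain at 0.41 in SZ-ABX against Ctrl in pgVAT, and with an estimated correlation none of these calls was kept.

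Over the 6 comparisons within tissues camera made 80 list calls, 42 up and 38 down, of which 0 were kept with an estimated correlation and 3 by fry. In scWAT 14, 11 and 15 lists were called for ABX against Ctrl, SZ-ABX against Ctrl and SZ-ABX against ABX, and other splits of these libraries gave medians of 10, 11 and 13 (highest 19, 20 and 22). RLE size factors changed the direction of none of these calls.

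Whether an effect differed between scWAT and pgVAT was tested in all 26 libraries. By edgeR 0 of 17909 genes were called for ABX against Ctrl, for SZ-ABX against Ctrl and for SZ-ABX against ABX, with 1060, 1071 and 1761 genes at an unadjusted p under 0.05 and smallest adjusted p of 0.726, 0.795 and 0.374. DESeq2 called 14, 3 and 31 genes, and voom with quality weights 0 in each. For SZ-ABX against ABX the difference of Cidea was −1.17 (SE 0.62), that of Adipoq −0.28 (SE 0.18) and that of Cox7a1 −1.04 (SE 0.74), none of them called. Among lists, the nuclear-encoded respiratory chain differed for SZ-ABX against Ctrl, lower in scWAT than in pgVAT (median difference −0.38, camera adjusted p = 4.61e-13), with an adjusted p = 0.894 with an estimated correlation. Interferon genes differed for ABX against Ctrl (median difference −0.28, camera adjusted p = 0.00219), with an adjusted p = 0.985 with an estimated correlation. The thermogenic list was not called in any of these tests, with median differences of 0.25, −0.19 and −0.41 and camera adjusted p = 0.553, 0.652 and 0.25.

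Ctrl libraries of the tissues differed in 6585 of 17909 genes, 3257 higher and 3328 lower in scWAT (n = 6) than in pgVAT (n = 3). The subcutaneous identity genes Shox2 (5.08, SE 0.30), Tbx15 (6.19) and En1 (3.27) were higher in scWAT, a list call kept with an estimated correlation (adjusted p = 0.0293). The mesothelial and visceral genes Upk3b (−11.79, SE 0.57), Upk1b (−10.24), Wt1 (−9.65), Msln (−9.53), Bnc1 (−8.13), Tcf21 (−7.51) and Lrrn4 (−3.80) were lower. The B cell genes Pax5 (6.28) and Cr2 (6.79) were higher in scWAT, as were the myelin gene Mbp (1.98) and Nlrc5 (1.52), a regulator of MHC class I genes. Of 25 thermogenic genes 21 were higher in scWAT and 0 lower (median 2.23, camera adjusted p = 7.62e-08), with an adjusted p = 0.202 with an estimated correlation. B cell (median 5.10, 16 of 18 higher) and T and NK cell markers (median 4.60, 18 of 19 higher) were higher as well, each with an adjusted p = 0.329 with an estimated correlation. Nerve markers, with 8 of 8 genes higher (median 2.37), kept their call with an estimated correlation (adjusted p = 0.0293).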

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

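Tests chosen only after the results were seen are the length and GC trend, the muscle score as a covariate, the comparison of interferon genes with immune cell lists, and the comparisons of adipocyte and other cell-type lists.

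Single scWAT libraries lay far from the others of their group in 18 of 273 groups of values tested, from 91 measures, where chance gives about 1 in 20. The pgVAT groups, of 3 libraries each, were too small for this test. SZ-ABX 4 stood apart in sterol synthesis (score 5.16, others 4.37 to 4.48), lipogenesis (10.04, others 8.91 to 9.12), the share of mitochondrially encoded counts (11.5%, 95% Wilson interval 11.475 to 11.508, others 7.02 to 8.60) and the share of its 10 most abundant genes (20.1%, interval 20.031 to 20.072, others 13.2 to 15.3). ABX 2 had a low thermogenic score (3.05, others 3.96 to 4.29), low Dio2 (3.12 CPM, interval 2.22 to 4.38, others 20.1 to 24.8) and low Ppargc1a (11.8 CPM, interval 9.91 to 14.1, others 17.3 to 18.5), with high Ces1f (339 CPM, interval 328 to 351, others 228 to 256). Ctrl 6 was high in interferon genes (score 5.04, others 4.61 to 4.77) and in Xaf1 (30.6 CPM, interval 27.4 to 34.1, others 20.7 to 22.8). SZ-ABX 6 was high in Lep (256 CPM, interval 247 to 266, others 36.6 to 106), in epithelial genes (score 0.85, others −1.52 to −1.06) and in visceral identity genes (−1.21, others −1.92 to −1.67). Ctrl 1 had a high share of its 10 most abundant genes (17.3%, interval 17.239 to 17.284, others 14.4 to 15.4) and a low mesothelial score (−1.64, others −1.43 to −1.32). ABX 5 was high in clock genes (5.43, others 4.55 to 4.78) and in the male genital tract list (−2.02, others −2.38 to −2.30), and SZ-ABX 3 in Dio2 (35.4 CPM, interval 32.6 to 38.4, others 5.33 to 16.3). Male genital tract, mesothelial and visceral identity scores were low in scWAT, where a few reads can move them.

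List effects differed between scWAT and pgVAT by camera with the preset correlation in 29 cases, and in none of them with an estimated correlation (adjusted p = 0.985, 0.894 and 0.682 to 0.716 for the comparisons in this order). For ABX against Ctrl the median differences, scWAT minus pgVAT, were 0.23 for fatty acid oxidation, 0.19 for lipolysis, 0.16 for adipocyte, 0.20 for matrix and 1.49 for mesothelial genes, and −0.28 for interferon, −0.77 for T and NK cell and −0.17 for mitochondrially encoded genes. For SZ-ABX against Ctrl they were −0.38 for the respiratory chain, −0.45 for mitochondrially encoded, −0.55 for lipogenic, −0.28 for sterol synthesis and −0.36 for glycolytic genes, and 0.41 for MHC class II and 0.45 for cell cycle genes. For SZ-ABX against ABX they were −0.41 for the respiratory chain, −0.29 for mitochondrially encoded genes, −0.37 for fatty acid oxidation, −0.74 for lipogenic, −0.40 for sterol synthesis, −0.26 for lipolysis, −0.39 for glycolytic, −0.27 for adipocyte and −0.41 for erythroid genes. In the same comparison they were 0.42 for interferon, 0.53 for MHC class II, 0.55 for cell cycle, 0.40 for macrophage and 1.21 for T and NK cell genes. Mesothelial scores were low in scWAT (−1.41 in Ctrl, −1.14 in ABX), and in pgVAT that of ABX 3 (2.59) was below those of ABX 1 (4.22) and ABX 2 (4.68). T and NK cell scores were low in pgVAT (−0.08 in Ctrl, 0.11 in ABX, −0.13 in SZ-ABX). The mesothelial and the T and NK cell differences between tissues are therefore uncertain.

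Interferon genes were lower in ABX than in Ctrl scWAT. With the B cell score as a covariate, for lymph node content of the pads, the median went from −0.46 to −0.37 (camera adjusted p = 2.42e-07; without the covariate, adjusted p = 0.506 with an estimated correlation). It went without Ctrl 6 from −0.38 to −0.19 and without ABX 3 from −0.44 to −0.28, so that a part of the fall may come from lymph node tissue. Fewer immune cells relative to adipocytes stay open, since the interferon score less the mean of the macrophage, T cell and B cell scores differed by 0.080 (95% interval −0.45 to 0.61). An effect of the antibiotics on interferon signalling cannot be told apart from these.

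Respiratory chain genes were higher in ABX and SZ-ABX than in Ctrl pgVAT. A length and GC trend between libraries is argued against as the whole cause, since with it removed the medians were 0.28 in ABX (0.32 before) and 0.37 in SZ-ABX (0.41 before). Without this correction the camera calls had an adjusted p = 0.352 and 0.55 with an estimated correlation. A higher adipocyte share may be a cause and stays open, as the macrophage score less the endothelial score differed by −0.23 in ABX (95% interval −0.41 to −0.056) and 0.18 in SZ-ABX (−0.064 to 0.43), and over 15 pairs of cell-type lists the lowest Bonferroni p was 0.322 and 1. The difference tried first, respiratory chain less adipocyte score, was 0.14 (−0.22 to 0.49) and 0.33 (−0.15 to 0.81) and decided nothing. An effect of the treatments was not told apart from this.

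The thermogenic list rose by camera in ABX against Ctrl scWAT (median 0.33), with an adjusted p = 0.62 with an estimated correlation, 0.349 by fry and 0 of 24 genes called by edgeR. Muscle RNA is argued against as the whole cause, since with the muscle score as a covariate the median was 0.36. It was 0.27 without the libraries high in muscle transcripts (camera adjusted p = 0.0426). Without Ctrl 3, the library highest in muscle transcripts, the covariate lowered the median from 0.27 to 0.23, and the call was lost (adjusted p = 0.0773). With the covariate it was also lost without Ctrl 6 (0.27, adjusted p = 0.087) or ABX 1 (0.23, adjusted p = 0.0537). A part from muscle is not excluded. A higher adipocyte share may be a cause and stays open, with a macrophage less endothelial difference of −0.50 (95% interval −0.93 to −0.064) and a lowest Bonferroni p of 0.434 over 15 pairs. The difference tried first, thermogenic less adipocyte score, was −0.023 (−0.90 to 0.85) and decided nothing. Chance was not excluded either, since 12 of 100 splits gave a median at least as far from 0.

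Splits of the libraries into other groups of the same sizes were set beside the counts. In scWAT 1 of 100 splits, the real one, gave as many called genes as ABX against Ctrl (122, highest other 89). This is a share under 0.05 of the splits drawn, 100 of 462. For SZ-ABX against ABX 2 of 100 splits gave as many called genes (220, highest other 639), a share under the same bound. In both comparisons the splits drawn always held the real one, and the share over all 462 may be higher. Neither count was stable. The count for ABX against Ctrl was 0 without ABX 2 or ABX 3, 2 without Ctrl 2 and 5 with the B cell score. For SZ-ABX against ABX it was 0 without 7 of the 17 libraries, 12 with the 2 groups alone and 0 with the B cell score. Chance is therefore not taken as excluded for either count. Another split with 639 genes, and one with 247 for SZ-ABX against Ctrl (0 genes by edgeR, 1519 at an unadjusted p under 0.05, DESeq2 28), point to a structure of the samples that was not tested. The split with 639 set ABX 2, 3, 4 and 5 with SZ-ABX 4 and 6 against the others, and so moved only 3 of 11 libraries from the real one. A real count of 0 is reached by each split (100 of 100), so that this comparison of splits says nothing about chance there. For the number of called lists chance was not excluded, with 21, 60 and 35 of 100 splits as large (14, 11 and 15 lists, highest other 19, 20 and 22). Nor was it for the absolute thermogenic median of SZ-ABX against Ctrl (0.051, highest other 0.57; 81 of 100) and against ABX (0.38, highest other 0.57; 10 of 100), and for ABX against Ctrl it was 0.33 with a highest other of 0.65.

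In pgVAT the 10 splits of 3 against 3 are too few for a share under 0.05. The counts of genes were 0 in each comparison by edgeR, with 1326, 1905 and 859 at an unadjusted p under 0.05 and 46, 322 and 1 by DESeq2, and the highest other was 0; each of the 10 splits reaches a count of 0, which says nothing. Called lists were 17, 10 and 13, highest other 15, 12 and 16 (1, 5 and 2 of 10 as large), and thermogenic medians 0.079, 0.24 and 0.095, highest other 0.20, 0.23 and 0.23 (9, 1 and 5 of 10). For the tissue differences edgeR found 0 genes (1060, 1071 and 1761 at an unadjusted p under 0.05; DESeq2 14, 3 and 31), a count that each of 100 splits reaches, so that the splits say nothing there (highest others 45, 5 and 0). For Ctrl scWAT against pgVAT 1 of 84 splits, the real one, gave 6585 genes (highest other 1375), so that chance is excluded.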

How the results depend on the processing

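The length and GC trend, the muscle settings and the permutation of list scores were chosen after the data were seen; the cause of the changes below was not tested unless stated. For ABX against Ctrl scWAT (122 genes) the count was 831 by DESeq2 (121 shared), 653 by voom with quality weights (122 shared), 447 with the 2 groups alone, 38 without a filter on low counts (more genes tested), 7 at a 2 fold change, 5 with the B cell score (4 shared), 63 with the muscle score (55 shared) and 46 without the libraries high in muscle transcripts (37 shared, fewer samples). For SZ-ABX against ABX scWAT (220) it was 1354 (218 shared), 1613, 12, 219 without a filter, 73, 0 with the B cell score (1308 at an unadjusted p under 0.05), 582 and 781. RLE size factors gave 142 and 200. DESeq2 called 28 genes for SZ-ABX against Ctrl scWAT, 46, 322 and 1 in pgVAT and 14, 3 and 31 for the tissue differences, where edgeR called 0, with 1519, 1326, 1905, 859, 1060, 1071 and 1761 at an unadjusted p under 0.05.

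With the replicate number as a block the scWAT counts were 250 (105 shared) and 943 (219 shared) and the thermogenic medians of ABX and SZ-ABX against Ctrl 0.32 and −0.06. The correlations gave no clear pairing by number: 9 of 25 within tissues and 6 of 27 between them were above 0.1, and the own number was best in 6 and 9. They cannot show whether equal numbers in the tissues stand for the same mouse. The 3 pairs of Ctrl scWAT and ABX pgVAT, groups not compared here, were each above 0.1 (0.12 to 0.53). Number 3 marked 3 of the 4 libraries high in muscle transcripts, with correlations of 0.40 to 0.53 among them.

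Of 80 list calls 0 were kept with an estimated correlation, 3 by fry and 5 lists passed the permutation of scores. The thermogenic medians of 0.33 (ABX against Ctrl) and −0.38 (SZ-ABX against ABX) in scWAT were not called with an estimated correlation (adjusted p = 0.62 and 0.487) or by fry (0.349 and 0.261). In pgVAT the B cell score gave thermogenic medians of 0.22 (adjusted p = 0.0113), 0.26 (0.0436) and −0.26 (0.19), and ABX against Ctrl was −0.036 with the muscle score and −0.037 without ABX 3. The B cell score in pgVAT was low and set ABX apart from the other groups, so that values with this covariate are uncertain there. The Pearson correlation of the ABX and SZ-ABX effects went from 0.219 to a mean of −0.205 with divided controls (−0.453 to 0.104 over the divisions).

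With each library left out in turn, counts ran from 0 to 292 (ABX against Ctrl), 0 to 13 (SZ-ABX against Ctrl) and 0 to 1770 (SZ-ABX against ABX) in scWAT, the highest without SZ-ABX 4, Ctrl 5 and SZ-ABX 4, and were 0 throughout in pgVAT by edgeR. Thermogenic medians ran from 0.22 to 0.49, −0.15 to 0.050 and −0.52 to −0.29 in scWAT and from −0.04 to 0.15, 0.01 to 0.26 and 0.01 to 0.24 in pgVAT. In pgVAT 22.4% of simulated genes changed by 1.5 fold were called, so that small changes there were missed more often than in scWAT (50.7%).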

Other observations

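No test in this part was chosen after the results were seen. Some lists were not called by camera in any of the 6 comparisons within tissues. Clock genes had medians of 0.18 in ABX and 0.096 in SZ-ABX against Ctrl scWAT (adjusted p = 0.263 and 0.965). Genes of glucocorticoid response had medians of 0.11 and 0.015 in scWAT (adjusted p = 0.263 and 0.361) and 0.31 and 0.25 in pgVAT (adjusted p = 0.061 and 0.165). Genes of heat-producing cycles that do not need Ucp1 had medians of −0.01 and −0.22 in scWAT (adjusted p = 0.405 and 0.224) and −0.16 and −0.09 in pgVAT (adjusted p = 0.23 and 0.978). Neutrophil markers, with 3 genes tested in scWAT and 2 in pgVAT, were not called either.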
